A study of Rattus norvegicus with 4 samples.

How the data were processed

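Per the labels, total RNA from the livers of 3 rats per condition was mixed, poly(A) RNA was purified from the mixture, and cDNA of the ANIT and the olive oil pool was labelled with Cy3 and Cy5 and hybridised together to a spotted cDNA array of rat genes. The authors deposited 1 value per feature and array, a log ratio of the 2 channels, read here as log2. Scanner, background correction, normalization, log base and direction of the ratio are not given in the sources used here. Array medians of -0.68, 0.31, -0.64 and 0.35 (arrays 1 to 4) show that the values were not centred on each array's median. Base 10 was set aside because the largest value, 4.96 in size, would exceed the largest ratio of a 16-bit scanner, 4.82 as log10. Natural logarithms stay open.

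The direction was taken as ANIT over olive oil on all 4 arrays, from the channel order in the labels alone. The equal sign of the largest ratios in both dye orientations showed only that the ratios already run the same way on all arrays, so no array's sign was turned; olive oil over ANIT would give the same picture. The expected behaviour of acute phase or other genes was not used to set the direction. Values were used as deposited, without further centring. Because the labels say that RNA was mixed, the 4 arrays were counted as technical repeats and each condition as 1 replicate. That all 4 arrays carry the same pools is a reading of the labels. The number of arrays limits the precision, and no intensity or detection flag was at hand to weigh single features.

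Features were named through the platform annotation paired with the value table, with symbols checked by gene ID against a RefSeq gene table of the rat assembly GRCr8. Of 1432 features with 1 symbol, 1429 matched, 3 kept the name of the annotation, and 0 symbols were updated. No gene was counted by name or in a list from the 19 features with several symbols or the 485 with none. The feature of Gstp1 and Gstp2 was mentioned after its value was seen.

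A feature was called higher or lower when its mean log2 ratio over the 4 arrays was at least 1 in size (2-fold) and all 4 arrays had the same sign. The SD over the 4 hybridisations is the error given, and it also holds any difference between the dye orientations. Further contrasts of the 4 arrays were formed, the dye contrast (Cy5 over Cy3) and a pair that holds neither treatment nor dye and measures hybridisation noise. Features with a dye contrast of -0.5 or below were called dye-shifted, a limit set after seeing the data. For lists, the features of a gene were averaged, the rule was applied to the gene mean, and the list's median was ranked among 10000 random lists of the same size (seed 1). Matching on intensity was impossible, and ranks matched on dye contrast in 5 bins were added after seeing the data.

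Before the data were examined, the 35 gene lists, the size rule and the rule for named genes were fixed. Named genes were up to 12 genes at each end among features past the rule with 1 symbol (the feature with the largest absolute mean), up to 4 members with the largest absolute ratio of each list with at least 3 measured genes, and the housekeeping genes. At the higher end 7 genes met the rule. Abcc2 and Cyp2e1 were added after their values were seen. Lists of genes of other tissues, of fasting genes and of carbonic anhydrases were also added after seeing the data, and appear in the closing section.

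Alternatives were other size limits, centring, single dye orientations, each array left out with a dye term, other log bases, the opposite sign, gene means, and limma across the 4 hybridisations with a dye term, which compares the pools and not the conditions. The steps were tested on simulated data for the ANIT against olive oil comparison over 1936 features. The size rule recovered 0% of changes of 0.5 log2, 100% of changes of 1.5, 2 and 3 log2, and called 0% of unchanged features. All these sizes lay well away from the limit of 1 log2 relative to the simulated noise. No change near the limit was simulated, so the reliability of calls close to it was not tested. In the same simulation limma (adjusted p limit 0.05) called 90% of changes of 0.5 log2 and 0.461% of unchanged features. Simulated unchanged features carried dye contrast and noise but no common offset, whereas the median ratio of the real features was -0.25. These rates therefore do not cover an offset in the real arrays. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.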

Results

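Liver transcripts were compared between rats given α-naphthylisothiocyanate (ANIT) and rats given its vehicle, olive oil, 24 h after a single intraperitoneal injection of 75 mg/kg. ANIT is a liver toxicant that injures the bile duct epithelium and is used in rodents as a model of cholestasis inside the liver. The animals were male Sprague-Dawley rats, and liver RNA of the 3 rats of each condition was mixed, which left 1 RNA pool per condition. Both pools were hybridised together on 4 spotted cDNA arrays as a balanced dye swap, with the ANIT pool in Cy5 on arrays 1 and 3 and in Cy3 on arrays 2 and 4. The 4 arrays are taken as technical repeats of the same pools, so the spread between animals is unknown. Every SD given here (n = 4 hybridisations) holds hybridisation error and any difference between the dye orientations. No p-value for the treatment is given, since each condition has 1 pool.

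Each array gave a log ratio for 1936 features, with no missing values. Of these features, 1432 carried 1 gene symbol and stood for 958 genes, 19 carried several symbols and 485 carried none. Ratios are given as ANIT pool over olive oil pool. This direction is likely rather than stated, and rests on the channel order alone: the labels list olive oil as channel 1 and ANIT as channel 2 on every array. The largest ratios had the same sign in both dye orientations, which speaks against Cy5 over Cy3 on every array but leaves olive oil over ANIT possible. The values were read as log2. The base of the logarithm is not given in the sources used here, and with natural logarithms each fold difference would be larger than printed. Spot intensities are likewise not given, so the signal behind each ratio is unknown.

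Among the lowest ratios in the ANIT pool were those of the carbonic anhydrases Car3 and Car2 and of several genes of fatty acid synthesis. Car3, a cytosolic carbonic anhydrase abundant in rat liver, was 23.7-fold lower (log2 ratio -4.57 ± 0.35), and Scd, the stearoyl-CoA desaturase, was 9.60-fold lower (-3.26 ± 0.30). Acsl1, which activates long-chain fatty acids, was 6.51-fold lower (-2.70 ± 0.22) and Fasn, the fatty acid synthase, 4.23-fold lower (-2.08 ± 0.13). The highest named genes were Lbp, the lipopolysaccharide-binding protein of plasma, at 3.36-fold (1.75 ± 0.12), and Mt1, a metallothionein that binds zinc and copper, at 3.22-fold (1.69 ± 0.40).

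In all, 74 features differed at least 2-fold in the mean with the same sign on all 4 arrays. Of these, 15 were higher and 59 lower in the ANIT pool, so that 79.7% were lower. With each array centred on its median, which moved the median of all features up by 0.17, the split was 22 higher and 48 lower, or 68.6% lower. Neither of the 2 array contrasts that hold neither treatment nor dye put any feature past the same 2-fold rule, nor past 1.5-fold. Among features with 1 symbol, 9 were higher and 52 lower, which came to 7 and 41 genes. Unnamed features split evenly, with 6 higher and 6 lower.

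Besides Lbp and Mt1, the genes higher in the ANIT pool were Cyp1a2, Alpl, Cavin3, Orm1 and Stat3. Cyp1a2, a cytochrome P450 inducible through the aryl hydrocarbon receptor, was 2.84-fold higher (SD 0.24 on the log2 scale, with the arrays between 1.29 and 1.84). Alpl, the tissue-nonspecific alkaline phosphatase whose serum activity is a clinical marker of cholestasis, was 2.62-fold higher (1.39 ± 0.18). Cavin3, a coat protein of caveolae, was 2.34-fold higher (1.22 ± 0.22), and Orm1, an acute phase glycoprotein, 2.09-fold higher (1.06 ± 0.29). Stat3, the transcription factor activated by interleukin 6, stood at the limit of the rule with 2.01-fold (1.00 ± 0.11). Without array 1, Orm1 had a log2 ratio of 0.97 and Stat3 of 0.98, both short of 2-fold, and Stat3 without array 2 had 0.97.

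Among the 12 lowest genes, Fgfr3, a fibroblast growth factor receptor, was 5.20-fold lower (-2.38 ± 0.36), and Tsc22d1, a transcriptional regulator, 4.98-fold lower (-2.32 ± 0.30). Fads2, the delta-6 fatty acid desaturase, was 4.85-fold lower (-2.28 ± 0.23). For several of these genes the features did not show the same difference. Car2, another carbonic anhydrase, was 12.0-fold lower on one feature (-3.59 ± 0.26) and had a log2 ratio of -0.03 on its other feature. Hao2, a peroxisomal hydroxyacid oxidase, stood at -1.95 ± 0.25 and 0.18, and Wt1, a transcription factor, at -1.89 ± 0.17 and 0.58. The bile acid and organic anion carrier Slco1a4 stood at -1.91 ± 0.37 and -0.10. Averaged over both features, Hao2 (-0.88) and Wt1 (-0.66) no longer reached 2-fold. Cyp8b1, named with the bile acid genes, stood at -1.89 ± 0.19 and -0.50.

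**Figure D1:**
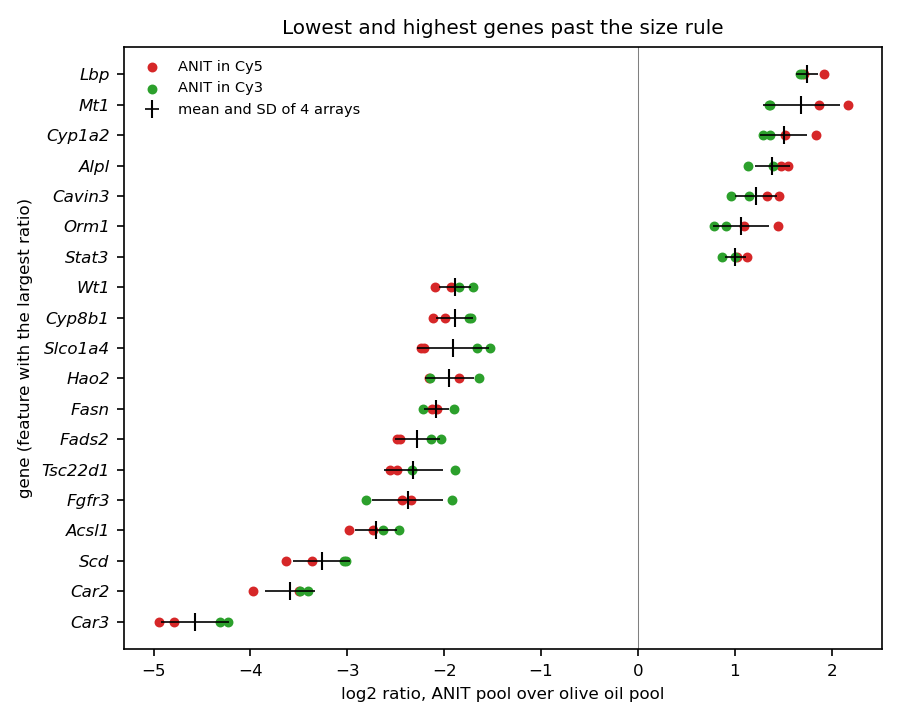
Log2 ratio (ANIT pool over olive oil pool) of the 12 lowest and the 7 highest genes past the 2-fold rule, with the 4 arrays as points, coloured by the dye of the ANIT pool, and the mean with its SD over the 4 hybridisations. Lbp (1.75) is the highest and Car3 (-4.57) the lowest, and every array of each gene lies on the same side of 0, as the rule requires.

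Gene groups were described by the mean over each gene's features, for 35 lists fixed before the data were examined. Of these lists, 32 had at least 3 measured genes, and together they held 273 of the 958 genes. The median over all genes was -0.24, and each list's median was placed among 10000 random lists of the same size as a description of these pools. The medians of 6 lists fell in the lowest 2.5% of random lists and those of 4 lists in the highest 2.5%. With centred arrays every list's median moved up by 0.17. In 20 of the 32 lists the median was below 0 with ANIT in Cy5 and above 0 with ANIT in Cy3. The sign was the same in both orientations for the other 12, which were bile acid synthesis, transporters, P450 enzymes, phase II enzymes, acute phase proteins, other plasma proteins, endoplasmic reticulum stress, fatty acid synthesis, gluconeogenesis and glycolysis, amino acid metabolism, oxidative phosphorylation and the proteasome. If the ratios ran the opposite way, every median would change sign and the order of the lists would be reversed.

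Fatty acid and triglyceride synthesis had the lowest median of the lists, -1.91 over 7 genes, below all 10000 random lists (percentile 0). In the ANIT pool 4 of its genes were lower, Scd, Acsl1 (gene mean -2.48 ± 0.31), Fasn and Fads2 (gene mean -1.91 ± 0.42), and none was higher. The genes of fatty acid oxidation and ketogenesis had no member past the rule and a median of -0.18 over 5 genes (-0.36 with ANIT in Cy5 and 0.24 with ANIT in Cy3), with Cpt1a, which admits fatty acids to mitochondria, at -0.51 ± 0.87. Cholesterol synthesis and uptake also had no member past the rule, and its members pointed both ways, with Dhcr7 at -0.59 ± 0.06 and Cyp51 at 0.37 ± 0.06. Its median over 6 genes was -0.08, and changed sign with centred arrays.

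Among the 15 genes of gluconeogenesis, glycolysis and glycogen, 2 were lower and none higher. Pklr, the liver pyruvate kinase, was 3.14-fold lower (-1.65 ± 0.15) and Gckr, the regulator of glucokinase, 2.83-fold lower (-1.50 ± 0.11). Pfkfb1 (-0.85 ± 0.48) and Pdk2 (-0.85 ± 0.16) did not reach 2-fold. The median was -0.45, at percentile 0.06, while the medians of the single arrays lay between -0.35 and -0.27. It was -0.29 with centred arrays and -0.30 with ANIT in Cy3 alone, and 5 genes were lower with ANIT in Cy5 alone or at 1.5-fold. The 4 genes of amino acid metabolism had a median of -0.60 (percentile 1.39, or 3.50 among lists matched on dye contrast) and no member past the rule, with Fah at -0.73 ± 0.12 and Got1 at -0.73 ± 0.46.

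All 3 measured genes of bile acid synthesis were lower in the ANIT pool. Cyp7a1, the rate-limiting enzyme of the classic pathway, was 3.04-fold lower (-1.60 ± 0.78), Cyp27a1, which starts the alternative pathway, 2.48-fold lower (-1.31 ± 0.18), and Cyp8b1, which makes cholic acid, 2.29-fold lower (-1.19 ± 0.65). The median was -1.31, at percentile 0.185. By gene mean, Cyp7a1 and Cyp8b1 differed between dye orientations, with dye contrasts (log2 of Cy5 over Cy3) of -0.67 and -0.56. In the arrays with ANIT in Cy3 alone 1 of the 3 genes reached 2-fold by gene mean. Both Cyp7a1 features followed the dye (-0.61 and -0.73). The Cyp8b1 feature at -1.89 had a dye contrast of -0.16 and lay between -2.11 and -1.72 on the 4 arrays. Its other feature, at -0.50, had a dye contrast of -0.96.

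Of 8 hepatocyte transporters, 3 were lower and none higher, with a median of -0.45 (percentile 1.35). The median was -0.94 with ANIT in Cy5 alone, -0.28 with centred arrays and -0.74 without dye-shifted features. Slc22a8, an organic anion transporter, was 3.50-fold lower (-1.81 ± 0.16), and Slc10a1, the sodium-dependent carrier that takes up bile acids from blood, 2.71-fold lower (-1.44 ± 0.04). Slco1a4 was lower at the limit of the rule (gene mean -1.01 ± 0.22), and Slco2b1 did not reach it (-0.74 ± 0.17). The number of lower transporters was 2 without array 1, with centred arrays and with ANIT in Cy3 alone. The canalicular pump Abcc2, which exports conjugated bilirubin, stood at 0.40. No gene among 13 liver nuclear receptors and transcription factors passed the rule (median -0.27, percentile 36.5). The bile acid receptor Nr1h4 had a ratio of -0.85 ± 0.46, and its target Nr0b2, a repressor of Cyp7a1, 0.62 ± 0.17.

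The list of cytochrome P450 enzymes of drug metabolism held 17 genes, among them Por, the P450 reductase, which is not itself a P450. Cyp1a2 was higher (gene mean 1.46 ± 0.19), Cyp2j3 (-1.17 ± 0.13) and Cyp4f4 (-1.12 ± 0.12) were lower, and 14 did not pass the rule. The median was -0.45, at percentile 0.04. The number of lower enzymes was 1 with centred arrays and 4 with ANIT in Cy5 alone or at 1.5-fold, and the median was -0.15 with ANIT in Cy3 alone. Cyp2e1, which did not pass by its gene mean, had 7 features from -1.24 to -0.10, of which 2 were lower by the rule. The 8 phase II conjugation enzymes had no member past the rule and a median of -0.40 (percentile 3.44; -0.17 with ANIT in Cy3 alone), with Mgst1 at -0.59 ± 0.24 and Gsto1 at -0.59 ± 0.06. A feature that carried both Gstp1 and Gstp2, glutathione S-transferases, stood outside the list because of its several symbols. It was 3.08-fold lower (-1.62 ± 0.37). Of 17 genes of the oxidative stress response, Mt1 alone passed the rule, while Nqo1 had a ratio of 0.48 ± 0.38. The median was -0.14 (percentile 88.7), and changed sign with centred arrays.

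Positive acute phase proteins had a median of 0.30 over 11 genes, above all 10000 random lists (percentile 100). This was the highest median of the lists, but not with ANIT in Cy3 alone, with features on their own (0.10, against 0.23 for the proteasome) or without array 1 (0.23, against 0.26 for the proteasome). Lbp and Orm1 were higher, none was lower, and the list had members on both sides of 0. Ceruloplasmin (Cp) stood at 0.57 ± 0.33 and A2m, a major acute phase protein of the rat, at -0.64 ± 0.59. Without array 1 the number of higher genes was 1. Among 11 negative acute phase and other secreted plasma proteins, Apoc1 (-1.20 ± 0.35) and Igfals, which binds insulin-like growth factors in plasma (-1.18 ± 0.11), were lower and none was higher, with a median of -0.22 (percentile 56.0). With ANIT in Cy5 alone 1 of these plasma proteins was lower. The 17 genes of inflammatory cytokines, chemokines and adhesion had none past the rule (median -0.14, percentile 87.4, sign changed with centred arrays), with Stat3 highest at a gene mean of 0.93 ± 0.09 and Il1r1 at 0.52 ± 0.07. The coagulation and complement list held 4 measured genes, Plat, Plau, Tfpi and Vtn, and no complement component, since C3 was listed with the acute phase proteins. None passed the rule (median -0.39), and 3 of the 4 were dye-shifted. The median was -1.07 with ANIT in Cy5 and 0.41 with ANIT in Cy3, so these genes say little about coagulation or complement.

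Endoplasmic reticulum stress and folding genes had a median of 0.15 over 10 genes (percentile 99.9; 0.061 with ANIT in Cy5 alone), with 7 members above 0 and none past the rule. Creld2 stood at 0.68 ± 0.28, asparagine synthetase (Asns) at 0.62 ± 0.27 and Xbp1, a transcription factor of the unfolded protein response, at 0.41 ± 0.09. Trib3 stood at 0.43 ± 0.56, with the arrays between -0.18 and 0.90. The members below 0 were Ddit3 (-0.16), Calr (-0.15) and Dnajb9 (-0.14). The proteasome had a median of 0.20 over 5 genes (percentile 99.1, or 95.8 among lists matched on dye contrast), with Psmd2 at 0.38 ± 0.11. The list of cytosolic ribosomal proteins had a median of 0.05 (percentile 99.7), and of 0.0024 to 0.10 with each array left out. Its pattern took 13 genes, among them Rps6ka4, a kinase, and Rpl17-ps16, a pseudogene. Without such genes, a list made after seeing the data, 9 were left with a median of 0.05 (percentile 99.0, or 96.5 matched on dye contrast). Heat shock proteins and chaperones (9 genes, median -0.03, sign changed with centred arrays), translation factors (8 genes, -0.22, kinases and a pseudogene included) and oxidative phosphorylation (3 genes, -0.17) had no member past the rule. With each array left out, the heat shock median lay between -0.018 and 0.0067 and that of oxidative phosphorylation between -0.24 and -0.11.

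**Figure D2:**
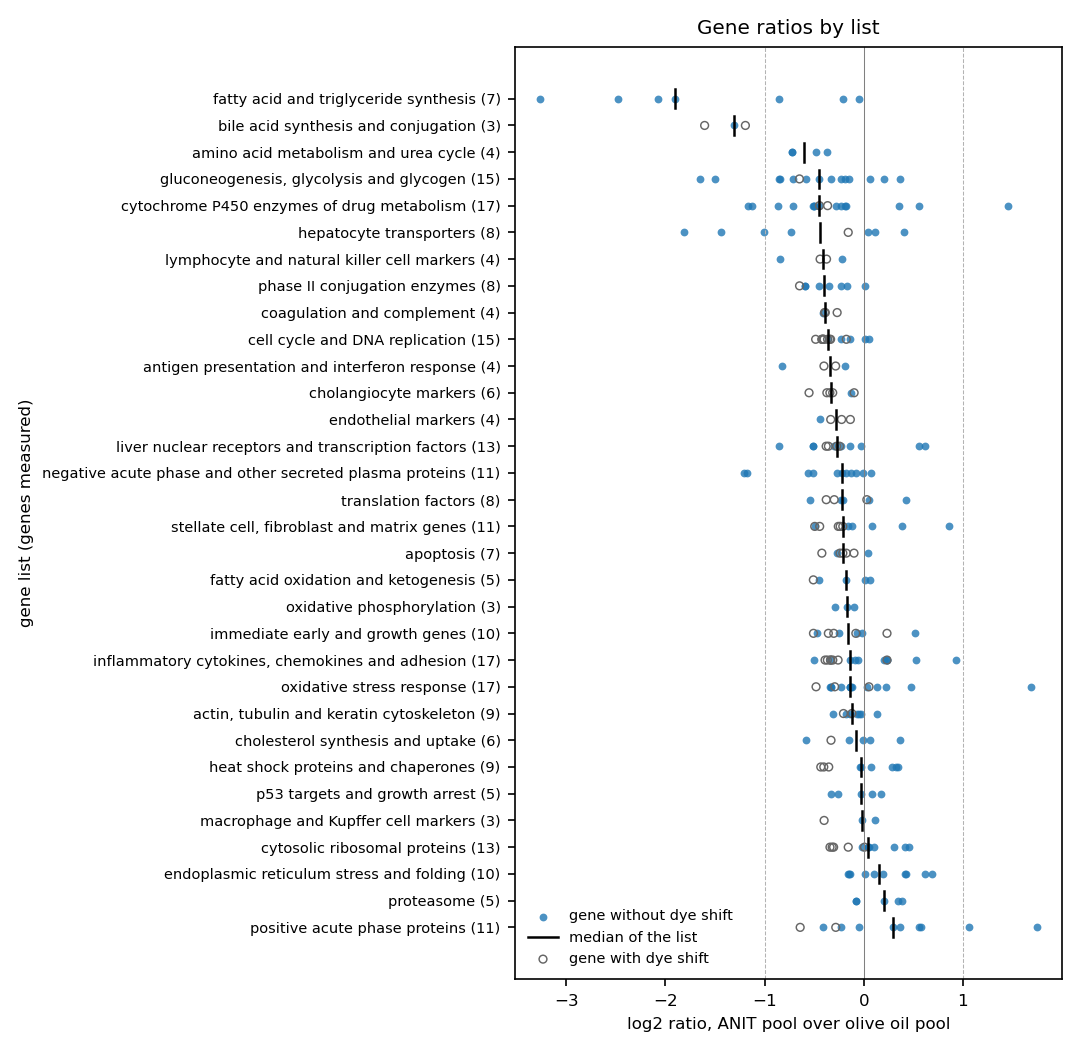
Log2 ratio (ANIT pool over olive oil pool) of each gene in the 32 lists with at least 3 measured genes, sorted by the median of the list (black bar), with dashed lines at 2-fold. Fatty acid synthesis (median -1.91) and bile acid synthesis (-1.31) lie lowest and positive acute phase proteins (0.30) highest, open circles are genes with a dye contrast of -0.5 or below, and 8 lists with medians near 0 change sign when the arrays are centred.

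The listed markers of cell types other than hepatocytes had no member past the rule, and many of them followed the dye. Genes outside these lists were not assessed as markers. Of 6 cholangiocyte markers (median -0.33), 5 had a dye contrast of -0.5 or below, among them Spp1 (-0.37 ± 1.15) and Ggt1 (-0.31 ± 1.11). The same held for 3 of 4 endothelial markers (median -0.28), 5 of 11 stellate cell, fibroblast and matrix genes (-0.21), 2 of 4 lymphocyte and natural killer cell markers (-0.41) and 1 of 3 macrophage markers (-0.01, sign changed with centred arrays). The only measured neutrophil marker, S100a9, was dye-shifted as well (-0.13 ± 0.89), and no red blood cell gene was measured under the symbols listed. Mmp14, a membrane-bound matrix metalloproteinase, was the highest of these markers at 0.86 ± 0.13, and Il2rb the lowest at -0.84 ± 0.12. The medians of all 5 lists of cell type markers had opposite signs in the dye orientations, for cholangiocyte markers -1.26 with ANIT in Cy5 and 0.49 with ANIT in Cy3.

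Cell cycle and DNA replication genes (15 genes, median -0.36, 10 dye-shifted) had no member past the rule, nor had apoptosis genes (7 genes, -0.21, 5 dye-shifted) or antigen presentation and interferon response genes (4 genes, -0.34), where Mx2 stood at -0.83 ± 0.14. Immediate early and growth genes (10 genes, -0.16), p53 targets (5 genes, -0.02) and genes of the cytoskeleton (9 genes, -0.12) had none either, and the medians of these 3 lists changed sign with centred arrays. Myc had a ratio of 0.52 ± 0.21. Of the housekeeping controls, Actb stood at -0.17 ± 0.21 and Hprt1 at -0.15 ± 0.39, and neither is shown by these ratios to be unchanged. Gapdh and the Lambda DNA spots were not analysed here, since no feature carried these names.

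The dye swap showed a dye effect in the deposited ratios. Array medians were -0.68 and -0.64 with ANIT in Cy5 and 0.31 and 0.35 with ANIT in Cy3. Across features, which are not independent replicates, arrays of one orientation correlated at r = 0.949 (arrays 1 and 3; rho = 0.942) and r = 0.940 (arrays 2 and 4; rho = 0.887). Between orientations r lay between -0.01 and 0.05 and rho between -0.35 and -0.29. Over the features with a dye contrast above -0.5, a choice that itself favours agreement, r between orientations was 0.71 to 0.77. The dye contrast put 0 features past 2-fold toward Cy5 and 238 toward Cy3. Its direction rests on the ratios being ANIT over olive oil. If they ran the opposite way, every dye contrast would change sign and the 238 features would lean toward Cy5. In total 837 features (43.2%) had a dye contrast of -0.5 or below. Of the features past the rule, 14 of the 15 higher and 53 of the 59 lower ones lay among the other 1099.

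**Figure D3:**
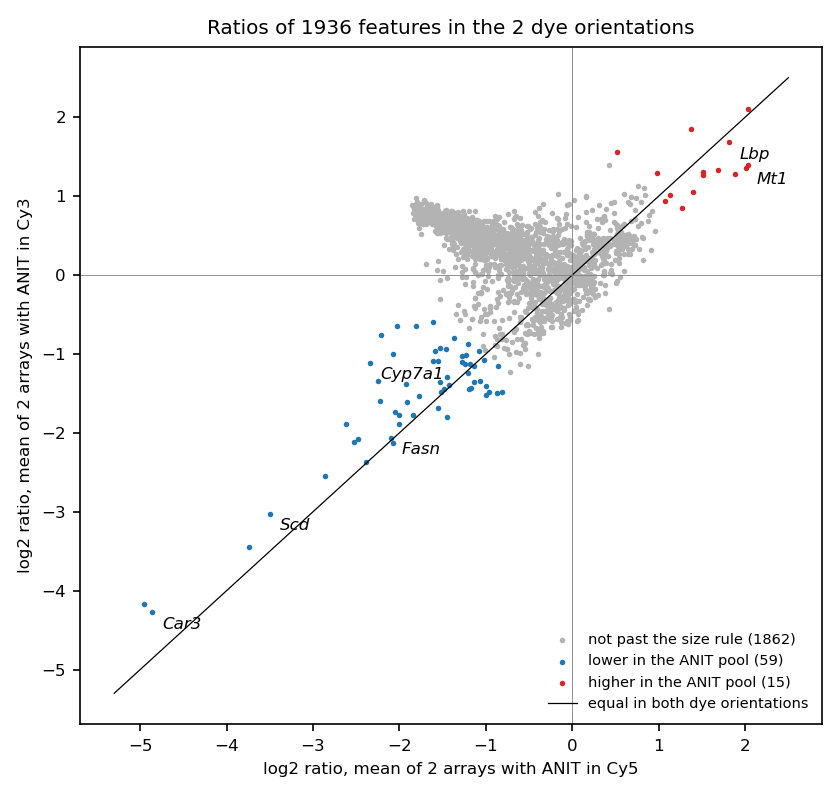
Mean log2 ratio (ANIT pool over olive oil pool) of each of the 1936 features in the 2 arrays with ANIT in Cy5 (horizontal) and in the 2 arrays with ANIT in Cy3 (vertical). The features past the rule lie along the diagonal, with 59 lower and 15 higher, while a cloud of 238 strongly dye-shifted features sits off it, with medians of -1.58 and 0.73.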

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

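The tests of the dye-related and lower-share patterns in this part were all chosen after the results they bear on had been seen. Dixon's test (gap to the nearest over the range) was run on values with 4 arrays each. In 7 of them an array stood apart from the other 3 by more than the critical value for 4 values. The tally of 179 values also holds the array counts of features 2-fold higher and lower, which were not put to this test. Chance gives about 1 in 20 for exchangeable values, a rate that does not strictly apply here because the arrays form pairs by dye orientation.

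Lbp was higher on array 1 (1.92) than on the others (1.67 to 1.71). Car2, on its low feature, was lower on array 3 (-3.98 against -3.50 to -3.40). Gsta2 was lower on array 2 (-0.62 against -0.41 to -0.38), and Mmp14 was less high on array 3 (0.67 against 0.91 to 0.93). Nkg7, a marker of natural killer cells, was at -1.17 on array 1 and between 0.03 and 0.15 elsewhere. Slc10a1 was at -1.37 on array 2 against -1.47 to -1.45, and the median of the gluconeogenesis, glycolysis and glycogen list was -0.27 on array 4 against -0.35 to -0.33.

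The ratios of 43.2% of the features followed the dye, and the 238 most shifted ones had a median of -0.43 with an SD of 0.07 over features. A reading of the values as Cy5 over Cy3 on every array, with this component as the treatment, was argued against by genes of other tissues and excitable cells, whose median dye contrast was -0.91 where that reading needs a value near 0. Weak hybridisation near background with a dye bias left in the values is consistent with the share of such genes that were dye-shifted, 83.3% (15 of 18), against 0 of 11 secreted plasma protein genes. It is not settled, since 2 of 11 acute phase and 2 of 9 ribosomal protein genes, among them Rps3 (dye contrast -0.78), and B2m (-0.88) were dye-shifted too, and no intensity was at hand. A biological explanation was not tested for this pattern, since the dye is not a group of the design.

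Of the 74 features past the 2-fold rule, 79.7% were lower in the ANIT pool. Hybridisation noise was argued against as the cause of the 74, since the larger noise contrast had 0. An offset of the dye-shifted features was argued against, since they held 5 of the excess of 44 lower over higher features, but weak hybridisation without a dye shift was not tested. Array medians away from 0 were argued against as the whole cause, since 68.6% were lower with each array centred on its median (63.2% to 72.5% with each array left out) and 74.2% with centring on the features without the dye shift (72.5% to 76.9%). A further offset of all values cannot be told apart from a lower level of many liver transcripts after ANIT, since no external standard was at hand: raising all values by 0.31 gave 33 higher and 33 lower, and some shift would do so in any such data.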

How the results depend on the processing

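The 12 lowest and 7 highest named genes all kept their sign under every setting run on them, but their selection left no other outcome. The rule asks for the same sign on all 4 arrays, which fixes the sign for left-out arrays and single dye orientations. Centring moved the values too little to turn a sign, and each gene mean holds the feature with the larger size. The kept signs are therefore no measure of stability. A 2-fold difference was kept by all 19 with centred arrays, with ANIT in Cy5 alone and without array 3 or 4. With ANIT in Cy3 alone and without array 1 each, 17 kept 2-fold (not Orm1 and Stat3), without array 2 it was 18 (not Stat3), and by gene mean 16 (not Stat3, Hao2 and Wt1). Settings added after seeing the data were the Cy5 over Cy3 reading, the dye-shift filters, and, for lists, features on their own. A filter on dim features was not run, since no intensity was at hand. The signal over background of each feature is unknown. Unless a setting's construction shows it, the cause of a change was not tested. The SD over the arrays holds the dye split, so it is no measure of stability between dye orientations. With ANIT in Cy5 or Cy3 alone, 20 of 32 list medians had opposite signs, among them endothelial (-0.97 and 0.45), stellate (-0.77 and 0.43), coagulation (-1.07 and 0.41) and inflammatory genes (-0.50 and 0.35).

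Features higher and lower (15 and 59 in the report) were 48 and 134 at 1.5-fold, 5 and 23 at 3-fold, 33 and 113 as natural logs, 181 and 259 as base 10 logs, 59 and 15 with the sign turned, 6 and 34 by gene mean, and 0 and 238 read as Cy5 over Cy3. With ANIT in Cy5 alone 667 were lower. Leaving out each array gave 13 to 15 higher and 58 to 61 lower. Features without the dye shift, centred on themselves, gave 17 and 49. At adjusted p under 0.05, limma, which measures hybridisation error only, called 275 higher and 1181 lower (280 and 1204 unadjusted), among the lower all 238 strongly dye-shifted features.

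With ANIT in Cy3 alone, bile acid synthesis had 1 lower gene and acute phase proteins 1 higher, and medians were -0.15 for P450 enzymes, -0.17 for phase II, 0.20 for oxidative stress, 0.41 for immediate early genes, 0.41 for heat shock, 0.17 for cholesterol, -1.54 for fatty acid synthesis, 0.24 for fatty acid oxidation, -0.30 for gluconeogenesis and glycolysis, -0.52 for amino acids, 0.36 for ribosomal proteins, -0.35 for oxidative phosphorylation and 0.44 for translation factors. With ANIT in Cy5 alone, 4 P450 enzymes, 1 plasma protein and 5 gluconeogenesis and glycolysis genes were lower, and medians were -0.94 for transporters, -0.48 for p53 targets, 0.061 for endoplasmic reticulum stress, -0.32 for gluconeogenesis and glycolysis and -0.52 for amino acids.

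With centred arrays, 1 P450 enzyme was lower, and medians were -0.24 for phase II, 0.46 for acute phase, -0.058 for plasma proteins, 0.31 for endoplasmic reticulum stress, -0.29 for gluconeogenesis and glycolysis, -0.44 for amino acids, -0.0058 for oxidative phosphorylation and 0.37 for the proteasome. At 1.5-fold, 4 P450 enzymes and 5 gluconeogenesis and glycolysis genes were lower. With features on their own, 5 bile acid and 6 P450 features were lower, and medians were 0.10 for acute phase, -0.33 for gluconeogenesis and glycolysis and -0.48 for amino acids. Without dye-shifted features the gluconeogenesis and glycolysis median was -0.39. Higher acute phase genes numbered 1 to 2 when each array was left out, with 1 without array 1. Ranked among lists matched on dye contrast, 5 lists lay in the lowest 2.5% (no longer amino acids) and 3 in the highest (no longer the proteasome).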

Other observations

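The tests in this part were chosen after the results had been seen, except that of clone assignment, which could not be run. Several genes lower in the ANIT pool stood outside the lists and were picked after their values were seen. The nucleoside transporters Slc28a2 (-1.37 ± 0.13) and Slc29a1 (-1.12 ± 0.16) were both lower, as was deoxycytidine kinase, Dck (-1.20 ± 0.31). Monoamine oxidase B, Maob, stood at -1.35 ± 0.35, the sulfurtransferase Tst at -1.21 ± 0.21 and the mitochondrial outer membrane protein Tspo at -1.16 ± 0.06. The vasopressin receptor Avpr1a stood at -1.65 ± 0.43, the inflammatory caspase Casp4 at -1.76 ± 0.24 on one feature and -0.15 ± 0.23 on the other, and angiogenin, Ang, at -1.22 ± 0.31 and -1.18 ± 0.36 on its 2 features.

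All 4 measured carbonic anhydrases had ratios below 0, and 3 were past the rule by gene mean: Car3 (-4.57), Car2 (-1.81) and Car1 (-1.80 ± 0.56), with Car4 at -0.65 ± 0.65. Both Car3 features were low, at -4.57 each, while the Car2 mean joins one feature at -3.59 and another at -0.03. Features within 0.1 of 0 on all 4 arrays numbered 50, of which 44 were unnamed, 9.07% of the 485 unnamed features against 0.414% of the 1451 named ones.

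Of 340 genes with several features, 23 had a feature past the rule. In 12 all features passed in one direction, in 11 only some did, and in 0 did features pass in opposite directions. The smaller-ratio feature was dye-shifted in 4 of the 11 genes and not in 7. Weak hybridisation of it stays open except in Stat3, described next, since no spot intensity was at hand. In Stat3 the features stood at 1.00 and 0.86, a range of 0.15, below the median range of 0.20 over genes with several features. There the 2-fold limit alone separates the features. Pfkfb1 also lay on both sides of the limit, at -1.09 and -0.62, with a wider range of 0.47. For the genes other than Stat3, clones assigned to the wrong gene or binding a related transcript cannot be told apart from true differences between transcripts. Clone sequences were not used here.

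A hypothesis for the lower fatty acid synthesis genes is that rats given ANIT ate less. As the whole cause this was not backed by genes raised by fasting, whose median was -0.51 over 3 genes (percentile 4.1 of random lists). Pck1 stood at -0.58 ± 0.51, Cpt1a at -0.51 ± 0.87 and Igfbp1 at -0.25 ± 0.11, against a median of -0.24 over all genes. None of the 3 was higher, but genes lowered by fasting were not tested as a group, so the question is not decided. With 3 genes the test is small, and Cpt1a followed the dye on one feature (dye contrast -1.27) but not on the other (-0.23). Food intake as a cause stays open. An effect of ANIT on the fatty acid synthesis genes themselves stays open as well, since food intake is not given in the sources used here.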
